A study of Arabidopsis thaliana with 6 samples.

How the data were processed

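The data are 6 Affymetrix ATH1 arrays of Arabidopsis floral buds, 2 each for the wild type and the mutants atyak1-1 and atyak1-2, grouped by their titles, which call the replicates biological. The deposited values are MAS5 signals, that is intensity on a linear scale, for 22810 probe sets, and GCOS and MAS5 are named, with no version, per the submitters' processing notes. The order of the authors' steps is not given in the sources used here. On the values themselves, the mean signal after trimming 2% at each end was between 499.81 and 499.83 on every array, so the arrays had been scaled to 1 level. Such scaling removes differences in overall brightness and assumes that the trimmed mean is alike in all samples. MAS5 gives small positive values to probe sets near background, and detection calls were not used here, so folds against dim signals are uncertain. The number of arrays limits the precision.

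The choices of tests, gene lists, naming rule and alternatives were made before the data were examined, except where the text says otherwise. Signals were taken to log2 with no further normalization and no pseudocount, 64 control probe sets were left out, and the third of the other 22746 probe sets with the lowest mean log2 signal was left out, which kept 15164 probe sets with a geometric mean signal of at least 73.6. Using limma 3.58.1 in R 4.3.3, 1 mean per genotype was fitted to all 6 arrays and the variances were moderated with a trend on mean signal, with 3 residual and 3.84 prior degrees of freedom. The contrasts were the mean of both alleles minus the wild type, each allele minus the wild type, and atyak1-2 minus atyak1-1. P-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

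Probe sets were named through the platform's probe table: 13513 had 1 gene, 503 had several and were not named, and 8794 had none listed. Of the probe sets with 1 gene, 13436 matched a current gene record. Among the names 88.3% are locus codes alone, and the fixed gene lists were thinly covered. AtYAK1 had 0 probe sets listed, and its level was not analysed here. In the lists, 4 members whose symbol belongs to another locus and 2 duplicates were left out.

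Genes named in the text were AtYAK1, had it been listed, and, for the main comparison, the 12 highest and 12 lowest log2 fold changes among named probe sets that passed, whose mutant arrays all lay beyond both wild-type arrays and whose mean signal was above the median of all probe sets (216). For the other contrasts the 5 highest and 5 lowest were taken by the same conditions, or up to 3 that did not pass where none did, and for each list up to 4 members by smallest p. Of several probe sets of a gene, the one with the highest mean signal stands for it. Genes outside this rule are said to have been chosen after their values were seen. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. The p-values of each set test were adjusted by Benjamini-Hochberg over the lists tested, which were 2 in the main fit.

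Samples that share a replicate number deviated together: the correlations of their deviations from the group means were 0.25 for the wild type with atyak1-1, 0.35 for the wild type with atyak1-2 and 0.61 for the alleles, so the numbers were taken to pair the samples. This evidence is weak, because with 2 replicates a group's deviations are mirror images, and 1 of the 4 ways to match the numbers across the groups makes all of these correlations positive. The pairing comes from the numbers in the titles and these correlations, as no shared batch is stated. The main model has no block, and the fit with the replicate number as a block is given beside the results that it moves. Other alternatives were no filter and a stricter filter, log2(signal + 32), quantile normalization, centring on the median, no variance trend, array weights, a fit to only the groups compared, a 2-group fit, a 2-fold criterion, and each array left out in turn.

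The fit was tested on simulated data made from the means and variances of 15164 probe sets. In the simulated main comparison, 62% of 50 probe sets changed by 1 log2 unit were recovered, and 100% of those changed by 2, 3 or 4, with 16 false calls. For atyak1-1 against the wild type 52% were recovered at 1 log2 unit, with 17 false calls, and for the difference of the alleles 64%, with 13 false calls. For the set tests the 7 tested late pollen genes were given a log2 shift of -2. In 100 simulated draws the shifted list was called each time by every set test. The unshifted list was called 5 times by camera, 0 times with an estimated correlation and 5 times by fry. The real late pollen list had a median of -1.58 and an SD of 1.84 between its genes, so these draws do not show how often such a list is called. The shared wild type was simulated in 100 draws of unchanged groups.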

Results

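Transcript levels were measured in floral buds of Arabidopsis thaliana on 6 Affymetrix ATH1 arrays, which carry short oligonucleotide probe sets for most genes of the plant. RNA came from mixed floral buds up to stage 13, taken from the primary inflorescence of 42-day-old Col-0 plants kept in equal periods of light and dark. Each of 3 groups, the wild type and the mutant lines atyak1-1 and atyak1-2, had 2 biological replicates on 1 array each. The mutants are different alleles of AtYAK1, a protein kinase of the DYRK family, and the study asked what AtYAK1 does in the development of the male gametophyte, the pollen. The values are MAS5 signals on a linear scale, and the number of arrays limits the precision of every comparison. The transcript level of AtYAK1 itself was not analysed here, because the probe table used for naming lists 0 probe sets for it, so the genotype labels were not checked against it.

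The arrays had like overall brightness, with median signals from 213 to 223. The ratio of 3′ to 5′ actin control signal, a measure of RNA integrity, was 1.91 and 1.58 on the wild-type arrays and between 1.43 and 1.68 on the mutant arrays. In a principal component analysis the first component held 60.2% of the variance and set the wild type, at -43.8 and -43.2, apart from the mutants, at 5.04 and 8.98 for the replicate 1 arrays and at 44.7 and 28.2 for the replicate 2 arrays of atyak1-1 and atyak1-2. The mutant arrays of replicate 2 thus lay farther from the wild type than those of replicate 1. The second component, with 21.7%, put the replicate 1 array above the replicate 2 array in each group, at 3.19 and -23.2 for the wild type, 28.3 and -19.8 for atyak1-1 and 23.1 and -11.6 for atyak1-2.

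The main comparison set the mean of both mutant alleles against the wild type. Most of the transcripts that passed the test were lower in the mutants. AtVEX1, a sugar transporter of the SWEET family known from the vegetative cell of pollen, fell from signals of 1420 and 2613 on the wild-type arrays to between 32.5 and 286.7 on the mutant arrays, a log2 fold change of -4.44 ± 0.80 (SE, 4 mutant against 2 wild-type arrays; adjusted p = 0.049, limma). AT1G10770, of the family of invertase and pectin methylesterase inhibitors, fell 19.1-fold (-4.26 ± 0.45, adjusted p = 0.0087). The sugar transporter SWEET13 fell 6.40-fold (-2.68 ± 0.28, adjusted p = 0.0082). In the other direction AT1G12010, which encodes an ACC oxidase of ethylene synthesis, rose 48.5-fold, from signals of 48.7 and 32.9 in the wild type to between 1303 and 3180 in the mutants (5.60 ± 0.34, adjusted p = 0.0014). The fold of AT1G12010 rests on wild-type signals below 73.6, the level under which probe sets were not tested, and with log2(signal + 32) its log2 fold change was 4.77. With each of the 6 arrays left out in turn, the highest adjusted p was 0.38 for AtVEX1, 0.13 for AT1G10770, 0.13 for SWEET13 and 0.0502 for AT1G12010. AtVEX1 had -5.23 without atyak1-1 replicate 1 and -3.66 without atyak1-1 replicate 2, and did not pass under a stricter signal filter (adjusted p = 0.067) or without the variance trend (0.077).

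Across the array, 292 of 15164 probe sets tested passed an adjusted p of 0.05 in limma's moderated test, 43 of them higher and 249 lower in the mutants. Over all probe sets tested, called or not, 3233 had every mutant array above both wild-type arrays and 1688 had every mutant array below both, where chance gives 6.67% in each direction, and the median log2 fold change was 0.09. As the contrast averages the alleles, it can call a change of 1 allele. Of the 292, 121 also passed in both alleles, 37 in atyak1-1 alone, 25 in atyak1-2 alone and 109 in neither. For 1 of the 292, AT1G53035, the alleles had opposite signs. Passing in 1 allele alone does not show that the alleles differ, and the test of that difference, given below, called no probe set. Of the 249 lower, 112 were at least 4-fold lower, against 9 at least 4-fold higher. The median log2 fold change was -1.80 among the probe sets called lower and 1.09 among those called higher. The median signal of the probe sets called lower was 782 and 754 on the wild-type arrays, 171 and 173 on the replicate 1 arrays of atyak1-1 and atyak1-2, and 135 and 154 on their replicate 2 arrays. Within replicate 1 this median change was -1.63 and within replicate 2 it was -2.08, and all 249 were lower in replicate 1 as well. The replicate 1 arrays were part of the fit that called these probe sets, so this is not a separate check. Those called higher changed by a median of 1.14 within replicate 1 and 1.03 within replicate 2. With the replicate number as a block, 1151 probe sets passed, 424 higher and 727 lower, and all 292 were among them. The count moved by over 1.5 times without any of 5 arrays: it was 8 without wild-type replicate 1, 7 without wild-type replicate 2, 100 without atyak1-2 replicate 1, 68 without atyak1-2 replicate 2 and 590 without atyak1-1 replicate 1. Without atyak1-1 replicate 2 it was 377. It was 113 under the stricter filter, 445 without the filter and 556 in a fit of 2 groups, mutant and wild type.

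**Figure D1:**
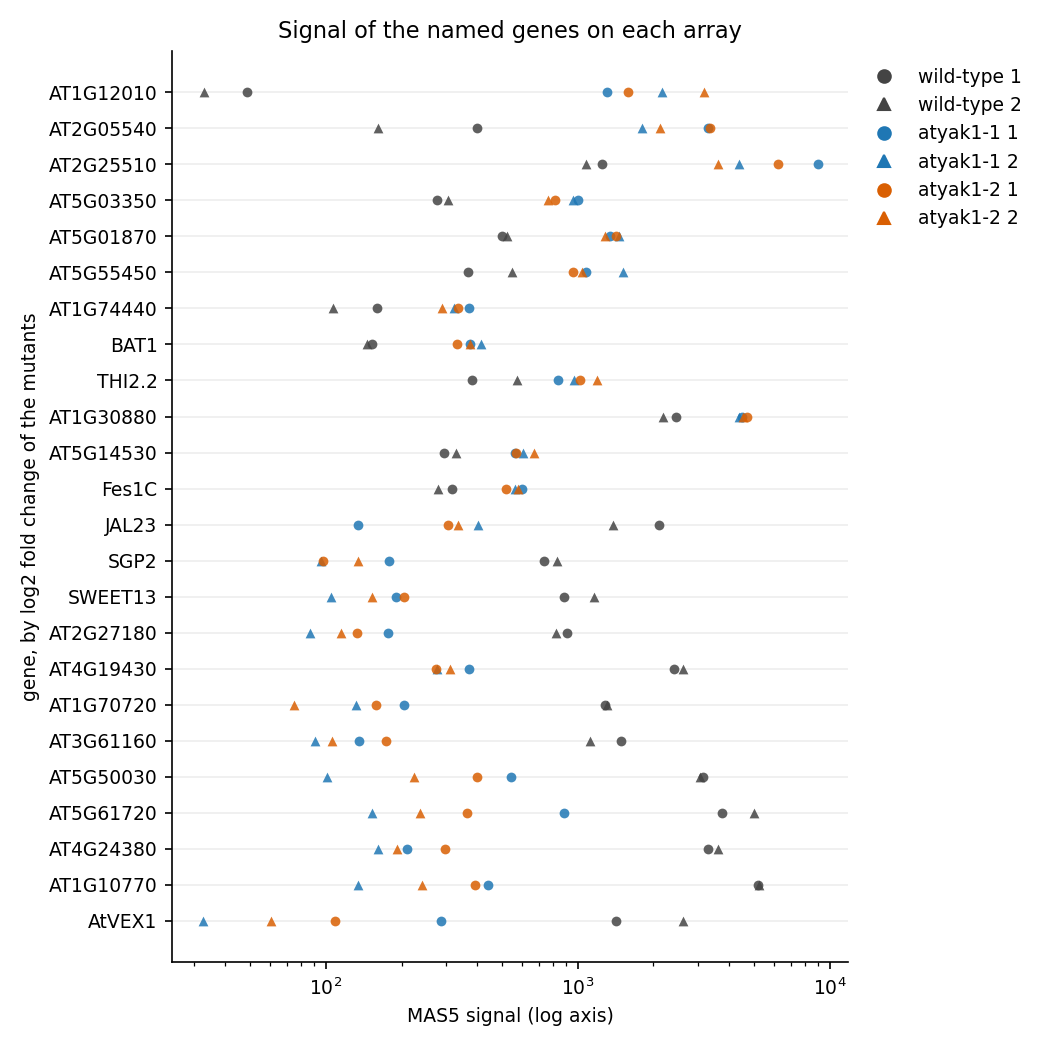
MAS5 signal, on a log axis, of the 24 genes named by the rule for the main comparison, with 1 point per array (grey wild type, blue atyak1-1, orange atyak1-2; circles replicate 1, triangles replicate 2), ordered by log2 fold change. For each gene the 4 mutant points lie on 1 side of both wild-type points, and AT1G12010, at 48.7 and 32.9 in the wild type, reaches 3180 in a mutant.

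The genes that rose after AT1G12010 were AT2G05540, which encodes a glycine-rich protein and rose 10.1-fold (3.33 ± 0.41, adjusted p = 0.014), and AT2G25510, which rose 4.70-fold (2.23 ± 0.32, adjusted p = 0.024). AT5G03350, a lectin of the legume type, rose 3.01-fold (1.59 ± 0.12, adjusted p = 0.0031). The lipid transfer protein genes AT5G01870 and AT5G55450 rose by log2 fold changes of 1.42 ± 0.12 and 1.33 ± 0.21. BAT1, an acyltransferase that acts on brassinosteroids, rose by 1.32 ± 0.14 and the thionin gene THI2.2 by 1.09 ± 0.19. AT1G74440, AT1G30880, AT5G14530 and Fes1C completed the rule's 12, with log2 fold changes of 1.33, 0.97, 0.95 and 0.92. Among the lower genes, AT4G24380 fell 16.4-fold (-4.04 ± 0.21, adjusted p = 0.00076) and AT4G19430 fell 8.20-fold (-3.04 ± 0.16, adjusted p = 0.00076). These were the 2 of the 24 named genes that passed whichever single array was left out. Without atyak1-1 replicate 1 and 2 in turn, AT5G61720 had -4.35 and -3.09 and AT5G50030 had -4.15 and -2.94, and without wild-type replicate 1 and 2 AT2G05540 had 3.98 and 2.68. Under the stricter filter the calls of AT5G61720, AT5G50030 and THI2.2 ended (adjusted p = 0.060, 0.063 and 0.065), without the variance trend so did those of AT5G61720, AT5G50030, THI2.2, AT5G55450 and JAL23 (0.066, 0.069, 0.074, 0.056 and 0.052), and THI2.2 also missed the threshold after quantile normalization (0.055) and median centring (0.0503), and in the fit of 2 groups without the replicate 2 mutant arrays (0.081). AT3G61160, a protein kinase of the GSK3/shaggy type, fell 10.5-fold (-3.40 ± 0.27, adjusted p = 0.0035), and the jacalin lectin gene JAL23 fell 6.24-fold (-2.64 ± 0.41, adjusted p = 0.032). AT5G61720, AT5G50030, AT1G70720, AT2G27180 and SGP2 had log2 fold changes of -3.72, -3.55, -3.28, -2.80 and -2.68. Fold changes of strongly lower genes rest on dim mutant signals: 66 of the 249 had a mutant mean under a signal of 73.6, the level below which probe sets were not tested.

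The list of late pollen and pollen tube genes had a median log2 fold change of -1.58, and its call in the camera set test was lost with an estimated correlation (adjusted p = 0.053). Of the 44 members of this list, fixed in advance, 10 had a named probe set and 7 were tested. All 7 had lower means in the mutants, 4 passed over all probe sets tested and 5 passed adjusted over the list alone. PLIM2a, an actin-bundling LIM protein of pollen, fell from signals of 1409 and 1267 to between 26.3 and 58.9 (-5.36 ± 0.33, adjusted p = 0.0014), and as these mutant signals are dim the size is uncertain, at -4.39 with log2(signal + 32). The receptor kinase gene AT4G39110 (BUPS1 in the list), also dim in the mutants, fell by 3.76 ± 0.42 on the log2 scale (adjusted p = 0.011), and had -2.82 with log2(signal + 32). The actin gene ACT12 fell by 1.58 ± 0.20 (adjusted p = 0.015), and AGL104, a MADS-box gene of pollen, by 1.56 ± 0.28 (adjusted p = 0.0497), a call that ended without the filter (0.056) and in the fit of 2 groups without the replicate 2 mutant arrays (0.058). The other 3 tested members were named after their values were seen. AGL66, with -1.87 ± 0.43, passed adjusted over the list alone (0.0047) and not over all probe sets (0.094), where it passed with the replicate number as a block (0.023). AGL30 and AGL65, with -0.63 and -0.06, passed neither, and AGL65 was at 0.02 after quantile normalization and at 0.18 without wild-type replicate 2. The median of the list was -1.58, against 0.10 for all 8187 named genes tested, and it was -1.11 within replicate 1 and -2.02 within replicate 2. The camera set test gave an adjusted p of 6.2e-10 with its preset correlation and 0.053 (unadjusted 0.027) with an estimated correlation, which was 0.25. In fry, which tests the list by itself, the adjusted p was 0.0060. With each of the 6 arrays left out in turn, the highest adjusted p was 0.084 for PLIM2a, 0.18 for AT4G39110, 0.19 for ACT12 and 0.41 for AGL104.

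**Figure D2:**
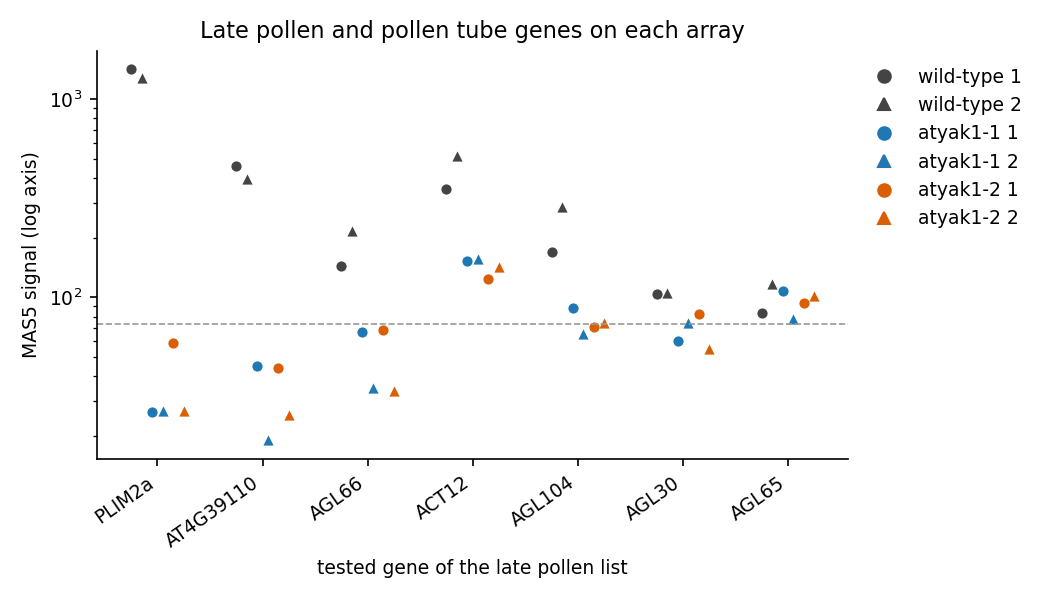
MAS5 signal, on a log axis, of the 7 tested genes of the late pollen list on each array (grey wild type, blue atyak1-1, orange atyak1-2; circles replicate 1, triangles replicate 2). The dashed line marks the signal of 73.6 that a probe set's geometric mean had to reach to be tested, and the mutant points of PLIM2a, AT4G39110 and AGL66 lie below it.

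Other pollen genes lay under the signal filter and were read from a fit without it, chosen after their values were seen. The pollen tube receptor kinase gene ANX2 had a geometric mean signal of 217 in the wild type, 11.2 in atyak1-1 and 13.7 in atyak1-2 (log2 fold change -4.14 ± 0.67, adjusted p = 0.032). Its relative ANX1 had -4.10 ± 0.77 and did not pass (adjusted p = 0.0505), nor did AT2G21480 with -2.17 ± 0.57 (adjusted p = 0.14). MGH3, a histone H3 gene of sperm cells and the 1 member of the sperm list with a named probe set, fell by 2.39 ± 0.41 on the log2 scale (adjusted p = 0.038).

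All 4 tested genes of tapetum and pollen wall, 2 of meiosis and 3 of early anther specification had higher means in the mutants, with list medians of 0.25, 0.34 and 0.43. Of the dimmer members of these lists, named after their values were seen and read from the fit without the filter, SPO11-2 and ROXY2 had -0.21 and -0.23, and ATSPO11-1, ZYP1b, SDS and RCK had 0.46, 0.11, 0.75 and 0.61, none of which passed. None of the 9 tested genes passed in limma, and 0 had an unadjusted p under 0.05. AMS, a regulator of the tapetum, had 0.27 ± 0.29 and SWEET8 had 0.39 ± 0.28. ATMND1 of meiosis had 0.47 ± 0.35 and SPL, which specifies sporogenous cells, had 0.44 ± 0.26. Without wild-type replicate 1 all 4 tapetum genes changed sign, with -0.04 for AMS, -0.14 for SWEET8, and -0.36 for both SHT and AT5G07230.

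The cell cycle inhibitors gave a list of 5 tested genes, of which 4 had lower means in the mutants, with a median of -0.40. In limma 0 passed, over all probe sets or adjusted over the list alone, and 2 had an unadjusted p under 0.05. AT5G02420 had -1.23 ± 0.41 (adjusted p = 0.21, and 0.026 with the replicate block), AT1G08180 had -0.53 ± 0.22, AT5G40460 had -0.40 ± 0.19 and SIM had -0.26 ± 0.14. The camera set test gave an adjusted p of 0.0070 with the preset correlation and 0.071 with an estimated correlation, and fry gave 0.033. The estimate was -0.086, below the preset of 0.01, so a larger correlation was not what ended the camera call. In the remaining lists 0 of 27 tested genes passed over all probe sets in limma, and 2 had an unadjusted p under 0.05. ALC, of the 3 tested carpel and ovule genes of which 2 were higher, passed adjusted over the list alone (0.64 ± 0.18, adjusted p = 0.028 there and 0.16 over all), as did COR47 of the 4 abscisic acid and drought genes (-0.97 ± 0.27, 0.039 there and 0.16 over all). With the replicate block COR47 passed over all probe sets (adjusted p = 0.0067), as did the clock gene CCL (0.41, adjusted p = 0.038). The 4 tested TOR pathway genes had a median of -0.31, with -0.04 ± 0.39 for ATG8E, which was at 0.45 without wild-type replicate 1, and 3 kinases related to AtYAK1, AME3, AT3G17750 and AT3G25840, had 0.12, 0.23 and 0.19. A dimmer relative, AT2G40120, also named after its value was seen, had -0.71 ± 0.28 in the fit without the filter and did not pass (adjusted p = 0.31). Cell division gave 1 of 3 higher (median -0.08), the circadian clock 2 of 2 (0.22), photosynthesis 1 of 2 (0.01) and flavonoids 1 of 2 (-0.10). The single tested genes of heat stress, wounding, cuticle and secondary wall had 0.34, -0.23, 0.10 and -0.16. With arrays left out in turn the last 3 changed sign: WRKY53 of wounding ranged from -1.56 to 1.10, SHN3 of cuticle from -0.11 to 0.31 and GUT2 of secondary wall from -0.44 to 0.12. The lists for pollen coat, sperm, floral organ identity, jasmonate and dehiscence, salicylic acid and root had 0 tested genes.

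The comparison of atyak1-1 with the wild type asked what this allele alone changes. AT1G12010 rose 41.8-fold (5.39 ± 0.39, adjusted p = 0.0042, 2 against 2 arrays in the fit to all 6), AT2G05540 by a log2 fold change of 3.27, AT2G25510 by 2.44, AT5G03350 by 1.75 and AT5G55450 by 1.51. AT1G10770 fell 21.5-fold (-4.42 ± 0.51, adjusted p = 0.017), and AT4G24380, AT3G61160, AT1G70720 and AT4G19430 had -4.22, -3.54, -2.99 and -2.97. None of these 10 genes passed with every array left out in turn: the highest adjusted p ran from 0.058 for AT4G24380 to 0.32 for AT2G25510. AT1G10770 had -5.28 and -3.57 without atyak1-1 replicate 1 and 2, and AT2G05540 had 3.92 and 2.62 without wild-type replicate 1 and 2. In all, 160 probe sets passed, 17 higher and 143 lower, against 81 in a fit to only the groups compared, 56 under the stricter filter and 242 without the filter. The calls of AT2G05540, AT2G25510 and AT5G55450 ended in the fit to only the groups compared (adjusted p = 0.088, 0.073 and 0.13), under the stricter filter (0.056, 0.068 and 0.076) and without the variance trend (0.061, 0.071 and 0.079). AT5G55450 also missed the threshold after quantile normalization (0.052), median centring (0.053) and with array weights (0.051). Of the 7 tested late pollen genes, 3 passed and 5 passed adjusted over the list alone, and the list's median was -1.53 (camera adjusted p = 1.1e-09, and an adjusted p of 0.055 with an estimated correlation). With the replicate block 789 probe sets passed, 211 higher and 578 lower. The count was 6 without wild-type replicate 1, 2 without wild-type replicate 2, 73 and 72 without atyak1-2 replicate 1 and 2, and 439 without atyak1-1 replicate 1.

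In atyak1-2 the same gene led the list of higher transcripts. AT1G12010 rose 56.1-fold (5.81 ± 0.39, adjusted p = 0.0028), AT2G05540 by a log2 fold change of 3.40, AT5G03350 by 1.43, AT5G01870 by 1.40 and BAT1 by 1.24. AT1G10770 fell 17.1-fold (-4.09 ± 0.51, adjusted p = 0.026), and AT4G24380, AT1G70720, AT3G61160 and AT4G19430 had -3.85, -3.57, -3.25 and -3.10. None of these 10 genes passed with every array left out in turn: the highest adjusted p ran from 0.071 for AT1G12010, AT4G24380 and AT4G19430 to 0.28 for BAT1, and AT2G05540 had 4.04 and 2.75 without wild-type replicate 1 and 2. In all, 146 probe sets passed, 15 higher and 131 lower, against 359 in a fit to only the groups compared and 50 under the stricter filter, where AT2G05540 missed the threshold (adjusted p = 0.052), as it did without the variance trend (0.057). The late pollen list again had 3 genes that passed, 5 adjusted over the list alone, with a median of -1.69 (camera adjusted p = 3.1e-10, and an adjusted p of 0.051 with an estimated correlation). With the replicate block 599 probe sets passed, 132 higher and 467 lower. The count was 0 without wild-type replicate 1, 2 without wild-type replicate 2, 27 and 14 without atyak1-2 replicate 1 and 2, and 361 and 356 without atyak1-1 replicate 1 and 2. Where it was 0 in limma, 1376 probe sets had an unadjusted p under 0.05.

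The effects of the alleles were set against each other gene by gene. Of the probe sets that passed in each allele, 112 were lower in both and 9 were higher in both, with 0 in opposite directions. Independent lists of these sizes would share 1.24 and 0.017, and simulated unchanged groups that share the wild-type arrays gave means of 0.04 and 0.07. The simulation draws each array independently, so it leaves out deviations that mutant arrays of 1 replicate number have in common, whose correlation between the alleles was 0.61. Across the 15164 probe sets, which are not independent replicates, the log2 fold changes of the alleles had Pearson's r = 0.93 and Spearman's rho = 0.81, against 0.50 and 0.47 in the simulation. The covariance was 0.285, against 0.034 from shared controls with no effect, a difference of 0.252 that also holds any such common deviation. With a different wild-type array for each allele, r was 0.75 and 0.72. With 1 array each, these last values still hold the arrays' own noise, and part of the excess in the calls may come from the shared controls or the shared replicate numbers.

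**Figure D3:**
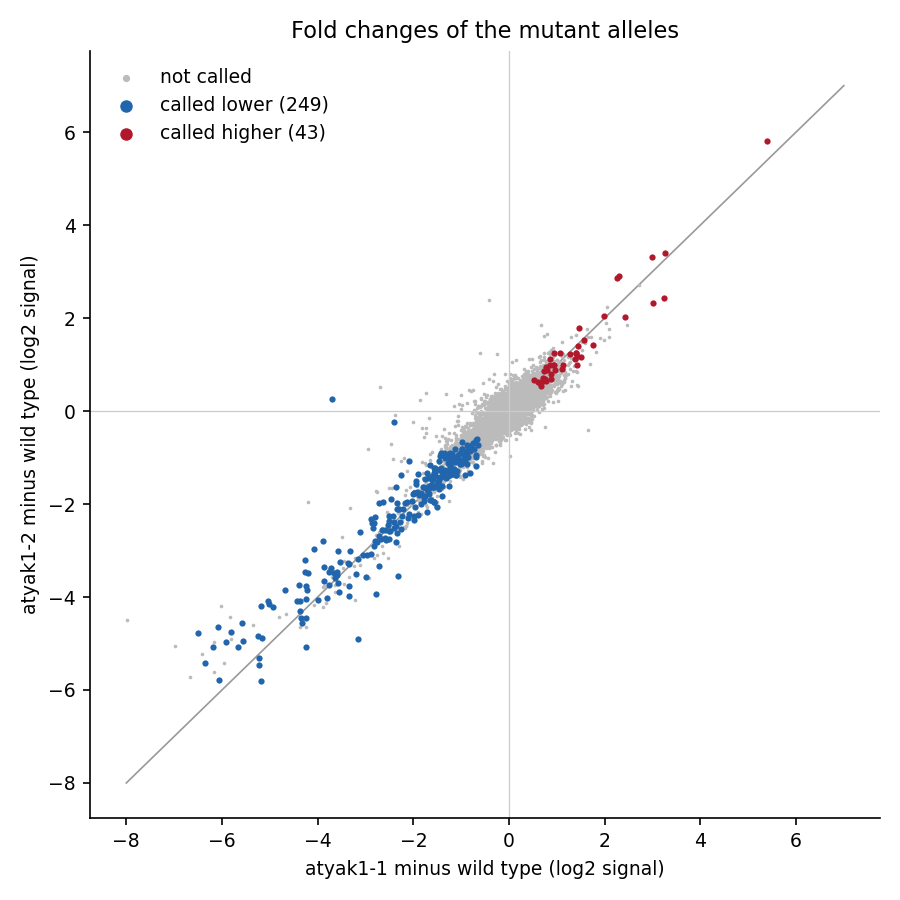
Log2 fold change against the wild type of atyak1-1 (horizontal axis) and atyak1-2 (vertical axis) for the 15164 probe sets tested, with 249 called lower (blue) and 43 called higher (red) in the main comparison and the line of equal change in grey. Most called points lie along that line, and the blue point at -3.71 on the horizontal and 0.25 on the vertical axis is AT1G53035.

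The difference between the alleles was also tested itself, as atyak1-2 minus atyak1-1. No probe set passed in limma, where 151 had an unadjusted p under 0.05 and the smallest adjusted p was 0.054, while 2 passed with the replicate block and 6 without atyak1-1 replicate 1. The median 95% half-width of the difference was 0.46 log2 units. The gene with that smallest adjusted p, AT1G53035, was named after its values were seen: its signals were 385 and 437 in the wild type, 29.8 and 33.1 in atyak1-1 and 365 and 652 in atyak1-2, a difference of 3.96 ± 0.29, with an adjusted p of 0.0015 under the replicate block. The other probe set that passed under the block is unnamed and had a difference of 2.16. By the naming rule, SCPL43, AT2G30740 and AT1G72290 had differences of 0.69, 0.69 and 0.68, and AT1G71180, AT5G07860 and AT2G07180 had -0.73, -0.72 and -0.53, none of which passed. The late pollen list had a median difference of 0.01 (camera adjusted p = 0.91) and the cell cycle inhibitors 0.04 (adjusted p = 0.91).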

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

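The alternatives were planned in advance, except the leaving out of both alleles' arrays of 1 replicate number, which was added after seeing the data. Counts below are in the order main comparison, atyak1-1, atyak1-2. Without the filter they were 445, 242 and 194 (281 of the 292 main calls were shared), and under the stricter filter 113, 56 and 50; the number of probe sets tested differs, and the cause was not tested further. With the replicate block they were 1151, 789 and 599, and 2 for the difference of the alleles; the block added AGL66, AT5G02420, COR47 and CCL to the named genes that passed, brought AT1G53035 past the threshold for the difference of the alleles, changed no other named call, and shared all 292, 160 and 146 main calls. In the fit to only the groups compared 81 passed for atyak1-1 and 359 for atyak1-2, and in the 2-group fit 556 passed in the main comparison, with 922 without the replicate 1 mutant arrays and 478 without the replicate 2 mutant arrays. A 2-fold gap between every array of the groups, with no model, gave 288 for atyak1-1, 321 for atyak1-2 and 3 between the alleles. Leaving out each array in turn gave ranges of 7 to 590, 2 to 439 and 0 to 361, and 0 to 6 between the alleles, with a lone array assumed to vary like the other groups. In the comparisons with the wild type the smallest counts came without a wild-type array, which leaves 1 wild-type array. The correlation of the alleles was 0.78 without the filter and ranged from 0.83 to 0.94 with arrays left out. An estimated correlation changes the test and not the medians, -1.58 for the late pollen list and -0.40 for the cell cycle inhibitors. With it neither list passed camera. With arrays left out the medians ranged from -1.94 to -1.30 and from -0.51 to -0.34. Under the stricter filter no list had 5 tested genes, so no value was obtained. Of 63 named results that passed above the filter, none changed direction under the alternatives run on them. Of these, 59 no longer passed without wild-type replicate 1, 61 without wild-type replicate 2, 32 and 41 without atyak1-2 replicate 1 and 2, 13 without the variance trend, 10 of 53 under the stricter filter, 3 of 20 in the fit to only the groups compared, 2 each after quantile normalization and centring, 1 each without the filter and with array weights, and 0 with the replicate block or log2(signal + 32). The other alternatives (the offset, quantile normalization, centring, array weights, no variance trend, and a 2-fold criterion on top of the adjusted p) kept the counts of the 3 comparisons with the wild type within 1.5 times the main ones. The alternatives for the transcript level of AtYAK1 were not run, as that level was not analysed here. Dim signals limit the folds of strongly changed genes in both directions: with log2(signal + 32), SWEET9 had -4.76 in place of -5.92 and AT1G12010 had 4.77 in place of 5.60.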

Other observations

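The genes in this paragraph were named after their values were seen. SWEET9, a sugar transporter needed for nectar secretion, was among the most strongly lower named genes, with signals of 1867 and 1289 in the wild type and between 15.4 and 35.5 in the mutants (log2 fold change -5.92 ± 0.39, adjusted p = 0.0019, limma). SWEET14 had -4.35 ± 0.38 (adjusted p = 0.0044), and of the 12 tested genes whose symbol begins with SWEET, which leaves out AtVEX1, 9 had lower means and 3 passed, SWEET9, SWEET13 and SWEET14. Of 31 families of like-named genes tested, a choice also made after the data were seen, 5 passed camera with its preset correlation, 2 passed fry, and 0 passed camera with an estimated correlation, where 2 had an unadjusted p under 0.05. The SWEET family had an adjusted p of 0.00010 with the preset and an adjusted p of 0.29 with the estimated correlation. Single genes that also passed as lower were the tubulin gene TUA1 (-1.09 ± 0.16), the LIM protein gene PLIM2b (-1.76 ± 0.27), the myosin gene XIE (-1.24 ± 0.18), the glycosyl hydrolase gene GH9A4 (-4.56 ± 0.44) and the expansin gene EXPB5 (-3.32 ± 0.51). The peptide gene RALFL25 had -5.34 ± 0.45. Dim mutant signals make some of these sizes uncertain, and with log2(signal + 32) RALFL25 had -4.12, SWEET9 -4.76, SWEET14 -3.64, GH9A4 -3.59 and EXPB5 -2.48. The gene BPEp, which limits petal size, had -1.35 ± 0.24 (adjusted p = 0.046). Smaller calls included GSTU20 (-0.90), the glucosinolate transporter gene GTR1 (-0.72) and the autophagy gene ATG8H (-1.52) among the lower, and BSH (0.84), a subunit of a chromatin remodelling complex, MAC3B (0.68) and DI21 (0.92) among the higher. None of the genes named here passed with every array left out in turn: the highest adjusted p ran from 0.084 for SWEET9, 0.097 for SWEET14 and 0.10 for RALFL25 to 0.24 for TUA1, 0.27 for PLIM2b and XIE, and 0.36 for BPEp, and GTR1 passed with none of the 6 left out. BPEp and GTR1 also missed the threshold under the stricter filter (adjusted p = 0.064 and 0.065) and, with MAC3B, without the variance trend (0.067, 0.076 and 0.066), and GTR1 in the fit of 2 groups without the replicate 2 mutant arrays (0.063).

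All tests in the next paragraphs were chosen after the results were seen. The first pattern is the excess of lower probe sets among the calls, 249 of 292, while over all probe sets tested 3233 had every mutant array above both wild-type arrays and 1688 below. After quantile normalization the probe sets called lower still had a median log2 fold change of -1.78, with quartiles of -3.02 and -1.28. As they were picked for their falls on arrays of like brightness, this could hardly have come out otherwise and does not decide on array scaling. Of 332 probe sets that passed in limma after that normalization, 283 were lower. The median over all probe sets tested was 0.088 there, so the small shift upwards was not removed, and its cause was not tested. A smaller share of late buds in the mutant samples may account for part of it and stays open, and it cannot be told apart from an effect on pollen itself. The 9 tested early genes, of tapetum, meiosis and early anther, had a median of 0.27. This was at the 96.5th percentile of 10000 random sets matched on signal, but at the 98.4th within replicate 1 and the 91.3rd within replicate 2. These percentiles measure spread between genes, with the early genes taken as independent, and not spread between arrays. Between the wild-type arrays alone these genes differed by a median of 0.64, replicate 2 minus replicate 1. Of the 15 splits of the 6 arrays into 2 and 4, the real split called 556 probe sets in the 2-group fit and 1 split, the real one, called as many, against 6 for the highest other, but 15 splits are too few for a share under 0.05. An effect of the mutations on pollen, the difference that the design names, remains a further open explanation.

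The second pattern is that the mutant arrays of replicate 2 lay farther from the wild type than those of replicate 1. Over the 183 probe sets at least 4-fold lower in the mutants, replicate 2 minus replicate 1 had a median of -1.12 in the mutants (-1.47 in atyak1-1, -0.86 in atyak1-2). The second principal component parted the replicate numbers in all 3 groups. Over these probe sets the wild-type arrays differed by a median of 0.011, with quartiles of -0.40 and 0.39. This argues against a batch that shifts these probe sets alike on all arrays of a number. A batch that acts on dim signals alone is not covered, as these probe sets were picked for being lower in the mutants. Wild-type RNA in the replicate 1 samples would need 1 share for all genes, fitted on the 142 of these probe sets with a wild-type signal above 500. For atyak1-1 the residual SD at the best share was 2.16 times the SD between the wild-type arrays at such signals (95% bootstrap interval 1.95 to 2.33). This lies above the bound of 1.5 set for a match, which argues against wild-type RNA as the only cause there. The best share was 8.6%, and wild-type RNA together with another difference between the replicates was not tested. For atyak1-2 the ratio was 1.15 (0.97 to 1.35) at a share of 3.1%, so a trace of wild-type RNA remains a candidate explanation there. For both alleles the interval resamples probe sets and does not measure spread between arrays. The SD leaves out a shift common to all these probe sets, and the ratio at a share of 0 was not compared. For atyak1-2 the test thus cannot tell wild-type RNA from other causes. A smaller share of late buds in the replicate 2 mutant samples cannot be told apart from other causes, because the early genes had medians of replicate 2 minus replicate 1 of 0.39 in the mutants and 0.64 in the wild type, with a median difference of 0.0045 and quartiles of -0.37 and 0.20.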
